A study of Mus musculus with 15 samples.

How the data were processed

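RNA from the heart of 15 mice was converted to double-stranded cDNA, labelled with Cy3 and hybridized to 1-colour NimbleGen mouse expression arrays, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per feature and array, which the authors summarized over the probes of a feature by RMA (background adjustment, quantile normalization and median polish), per the submitters' processing notes, which name RMA without a version or settings. The series value table held the same intensities as the files per array (0 cells differed). Quantile normalization gives the arrays nearly equal distributions, so a shift shared by most genes would not be seen, and very bright genes are compressed. Each array held 44171 features, of which 44155 had 3 probes and 1 was a random-sequence control. The level of that control (91.1 to 128.9) served as the gauge of background, since no detection flags were used here. Between 62.2% and 69.7% of the features of an array lay above 2 times that level. This gauge was applied to the 106 genes named here after their values were seen. In 6 of them (Bub1, Fgf21, Polg2, Ppp1r3a, Snap25 and Wdcp) a whole group was not above 2 times the level, and these are given without a difference or with a lower bound. In 10 others some arrays of a group were not above it, so the sizes of their differences are uncertain: Arhgap5, Csnk1g1, Elane, Esrrg, Ntsr2, Prkca, Rhox2b, Setd7, Th and Xlr5b. All per-sample columns were matched to a sample.

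Groups were taken from the genotype and treatment in the labels. The control feature was left out and log2 was taken of the intensities with no pseudocount and no filter on dim features. Gene names were updated through the Entrez identifiers in the files with a RefSeq gene table of mouse assembly GRCm38.p6, used for names only: 39057 features were named in this way, 2829 kept the file's name and 2284 had no gene name. Coordinates are those of the files, on build MM9, and are the span the files give for the feature. For the 10215 genes with more than 1 feature, the feature with the highest mean over all arrays was used, which left 26455 genes and unnamed features, 24171 of them named. Some genes of the lists were not analysed here, and 1077 of 1128 list members were measured.

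The 4 groups were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and 5 contrasts were tested: AZT against vehicle in each genotype, MCAT against wild-type under each treatment, and the difference between the AZT responses. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all 26455 rows, and the test was two-sided. Gene lists, 47 in number, covering mitochondrial, metabolic, stress, chromatin and cell type marker genes, were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. Lists and comparisons share genes and arrays: the AZT-treated MCAT arrays enter 3 of the contrasts, so calls in them are not independent of each other. Contrasts, thresholds, lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

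The rule for named genes took the 10 largest increases and decreases among genes past the threshold, with a single gene name that is not a predicted or clone name and a group mean above the median of all features. Where fewer than 10 genes passed, it took the 10 with the smallest p, given as values that did not pass. It also took up to 4 members with the smallest p from each list that passed, or that had 2 or more members past the threshold, and 11 genes in every comparison: Cat, Nppa, Nppb, Myh7, Ppargc1a, Gdf15, Fgf21, Cdkn1a, Sod2, Tk1 and Tk2. The list members given by name are a part of those the rule took, picked after their values were seen. Sex-linked and atrial transcripts were examined as checks of the samples, and those given by name were chosen after their values were seen.

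The fit was tested on simulated data made from the means and residual spreads of the 26455 rows with 200 changed genes in each comparison. At a log2 change of 2 it recovered 70% of 100 changed genes for AZT in wild-type hearts, 66% for AZT in MCAT hearts, 70% for MCAT under vehicle, 76% for MCAT under AZT and 34% for the difference between the responses. At a log2 change of 1 it recovered 22%, 21%, 20%, 11% and 1% in the same order. A list shifted by design was called in each simulated comparison, with 0 other lists called. Between 4 and 6 unchanged genes were called in a comparison. The simulated genes varied independently of each other, while list correlations estimated from the data ran up to 0.88. The simulation thus cannot gauge false calls of genes or lists among correlated genes, nor how recovery would vary with them. Other splits of the real arrays called up to 2589 genes for MCAT under vehicle and up to 2013 for MCAT under AZT.

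Replicate numbers are shared across groups in the labels. The correlation between the deviations of same-numbered arrays from their group means ran from -0.51 to 0.37 for AZT in wild-type hearts, from 0.03 to 0.4 for AZT in MCAT hearts and from -0.47 to 0.51 for MCAT under AZT, so pairing by number was not shown there. The values of -0.51 and -0.47 were those of replicate 2, which in AZT-treated wild-type lacked the Y-linked transcripts that its partners carried. For MCAT under vehicle all 4 pairs lay between 0.3 and 0.5, over the minimum of 0.1 set for pairing, but the same-numbered array was the best match in 1 of 4. In these groups arrays 1 and 2 carried Y-linked transcripts and arrays 3 and 4 did not. The correlations may thus reflect that split, and neither show nor rule out pairing, which the labels do not state.

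The arrays came from 2 slides, read from the identifiers of the arrays. Slide 2 held 1 array of each group and slide 1 held the other 11, so slide was fitted as a block. Alternatives covered the slide, the replicate number as a block, only slide 1, only the groups compared, another quantile normalization, median centring, an offset of 50 before log2, a filter on dim features, the series value table, every feature by itself, the mean of the features of a gene, eBayes with trend and robust settings, array weights, other thresholds and leaving out each array. A background correction of raw intensities was planned and not run, since raw intensities were not analysed here. An array was taken to carry Y-linked transcripts where log2 Ddx3y was above 8, and fits with that as a block or within these arrays were chosen after seeing the data. Expression was the only assay analysed here, and methylation arrays were not used.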

Results

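Transcript levels were measured in hearts of 15 C57BL/6 mice, which the labels give as left ventricle, on a 1-colour NimbleGen expression array with 1 mouse per array, so the replicates were separate animals. The mice were wild-type or carried MCAT, a transgene for catalase directed to mitochondria, where the enzyme breaks down hydrogen peroxide. They received AZT (zidovudine, a thymidine analogue used against HIV that is known to impair mitochondrial DNA replication) or the vehicle, carboxymethylcellulose. There were 4 vehicle-treated wild-type, 3 AZT-treated wild-type, 4 vehicle-treated MCAT and 4 AZT-treated MCAT hearts, and the number of arrays limits the precision. The title of the series places the comparisons in the question of how oxidative stress from mitochondria alters expression in the heart. The median intensity of an array lay between 434.3 and 462.1, and the level of the random-sequence control probes lay between 91.1 and 128.9. Values are log2 RMA intensities, and differences are log2 differences with the standard error from limma.

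Cardiac muscle transcripts were near the top of the scale on all 15 arrays, with Myh6 (alpha myosin heavy chain) between 15.31 and 15.54 and Tnni3 (cardiac troponin I) between 15.12 and 15.44. In contrast, the arrays of every group fell into distinct sets by sex-linked and atrial transcripts. The Y-linked gene Ddx3y lay between 11.01 and 11.83 on 7 arrays and between 5.58 and 6.02 on the other 8. Xist, the X-inactivation transcript, lay between 6.52 and 8.19 on those 7 arrays and between 12.84 and 14.02 on the 8. The atrial light chain gene Myl7 lay between 14.99 and 15.38 on the same 7 arrays and between 7.09 and 8.99 on the 8, and Sln (sarcolipin, an atrial regulator of the calcium pump) between 13.46 and 14.99 against 6.88 and 8.22. The 7 arrays were 2 of 4 vehicle-treated wild-type, 1 of 3 AZT-treated wild-type, 2 of 4 vehicle-treated MCAT and 2 of 4 AZT-treated MCAT hearts. This split took 37% of the variance, where any split of that kind would take 7.1% by chance, and the 4 groups took 14.8%, where 21.4% was the chance value.

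**Figure D1:**
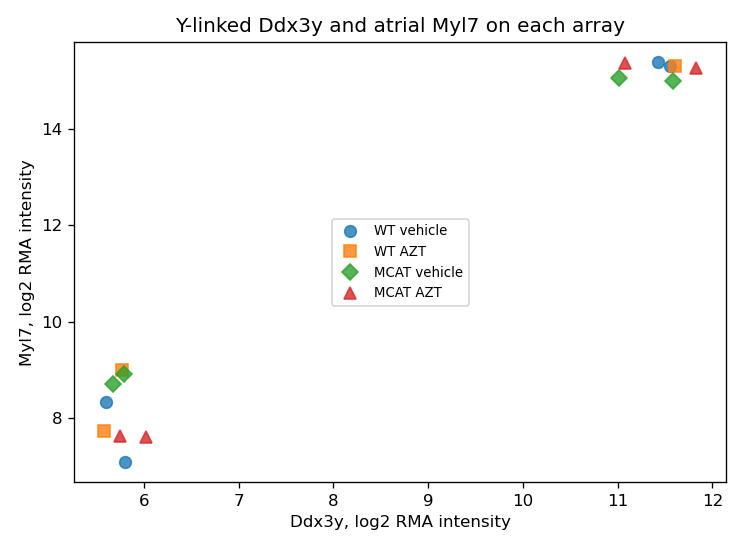
Level of the Y-linked gene Ddx3y (x axis) against the atrial gene Myl7 (y axis) on each of the 15 arrays, both as log2 RMA intensity; each symbol is an array and its shape and colour give the group. Myl7 lay at 14.99 or above on the 7 arrays with Ddx3y at 11.01 or above, and at 8.99 or below on the other 8, and every group had arrays of both kinds.

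AZT against vehicle in wild-type hearts asks what the drug changed without the transgene. The mitochondrial gene lists named next lay slightly lower under AZT over all arrays, while dynamics and mitophagy did not pass (median -0.08, adjusted p = 0.1). Within the 7 arrays with Y-linked transcripts, of which only 1 was AZT-treated wild-type, camera's direction turned for 10 lists. Camera compares a list with all other genes, and this fit was chosen after seeing the data. There the medians of the tricarboxylic acid cycle and fatty acid oxidation lists were near 0, at 0.03 and -0.00. Over all arrays the tricarboxylic acid cycle list had a median log2 difference of -0.17, with 20 of 23 measured members lower (camera adjusted p = 0.0042). The fatty acid oxidation list had a median of -0.14, with 25 of 29 members lower (adjusted p = 0.0071), and the regulators of mitochondrial biogenesis a median of -0.26, with 9 of 13 lower (adjusted p = 0.0077). The interferon response list lay higher by a median of 0.25, with 28 of 33 members higher (adjusted p = 0.0042). These 4 calls did not hold with a correlation estimated from the data (adjusted p = 0.74 with an estimated correlation for each). No single gene of the 26455 tested passed limma's adjusted threshold.

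Among the 20 measured genes for maintenance and transcription of mitochondrial DNA, 13 were lower, with a list median of -0.13 (camera adjusted p = 0.0049). The examples did not pass individually: Slc25a33, a mitochondrial carrier of pyrimidine nucleotides, differed by -1.13 (SE 0.39), Mgme1, a mitochondrial exonuclease, by -0.49 (SE 0.23), and Tfam, which packages mitochondrial DNA, by -0.58 (SE 0.36). Of the biogenesis regulators, the nuclear receptor gene Esrrg differed by -0.93 (SE 0.59) and the fatty acid receptor gene Ppara by -0.59 (SE 0.47). Suclg2 and Idh3a of the tricarboxylic acid cycle differed by -0.45 (SE 0.42) and -0.38 (SE 0.3), and Etfa and Acadl of fatty acid oxidation by -0.31 (SE 0.28) and -0.27 (SE 0.27). Etfa and Acadl stood at -0.11 and -0.09 without AZT-treated wild-type replicate 2, Suclg2 at -0.13 without replicate 3 of that group, and Idh3a and Tfam at -0.18 and -0.37 without vehicle-treated wild-type replicate 4. Ppara stood at -0.35 without vehicle-treated wild-type replicate 3. Within the arrays with Y-linked transcripts Tfam, Esrrg, Ppara, Suclg2 and Etfa (0.11) had the other sign. The mitochondrial ribosome list had a median of -0.12, with 33 of 46 members lower (camera adjusted p = 0.0077), but 0.04 without vehicle-treated wild-type replicate 4. Complex I had a median of -0.06 (25 of 36 lower, adjusted p = 0.043) and complexes II to V -0.04 (27 of 42, adjusted p = 0.034). Without AZT-treated wild-type replicate 2 complexes II to V stood at 0.01. Each of these 3, like the mitochondrial DNA list, had an adjusted p = 0.74 with an estimated correlation. In the methionine and one-carbon list, which supplies methyl groups, 16 of 22 members were lower with a median of -0.21 (adjusted p = 0.0042, and adjusted p = 0.13 with an estimated correlation). Its members Mthfd2l and Mat2a differed by -0.7 (SE 0.34) and -0.35 (SE 0.24). In the interferon list, Irf7, a transcription factor of that response, differed by 0.63 (SE 0.35), Gbp3 by 0.65 (SE 0.41) and Igtp by 0.56 (SE 0.37). Gbp3 stood at 0.41 without vehicle-treated wild-type replicate 4. Igtp stood at 0.11 without AZT-treated wild-type replicate 2 and at -0.03 within the arrays with Y-linked transcripts.

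The cytosolic ribosome list was also called lower, with 41 of 49 members lower and a median of -0.07 (adjusted p = 0.0042), with Rpl24 at -0.35 (SE 0.27) and at -0.14 without vehicle-treated wild-type replicate 4. The circadian clock list had 14 of 18 members lower and a median of -0.14 (adjusted p = 0.012). Its repressor genes Nr1d1 and Nr1d2 stood at -0.43 (SE 0.35) and -0.55 (SE 0.39). Nr1d1 stood at -0.10 without AZT-treated wild-type replicate 3, and Nr1d2 at -0.23 without vehicle-treated wild-type replicate 3. The list of mitochondrial and cytosolic protein folding had 21 of 29 members lower and a median of -0.1 (adjusted p = 0.0077), with Hsph1, a heat shock protein gene, at -0.85 (SE 0.36). Hsph1 stood at -0.40 without AZT-treated wild-type replicate 2 and at 0.05 within the arrays with Y-linked transcripts. The immediate early genes had a median of -0.27 (20 of 23 lower, adjusted p = 0.0042). The glucocorticoid and fasting genes had a median of -0.28 (17 of 20 lower, adjusted p = 0.0048), with the muscle ubiquitin ligase gene Fbxo32 at -0.79 (SE 0.35) and at -0.38 without AZT-treated wild-type replicate 3. The endoplasmic reticulum stress list had a median of -0.18 (16 of 19 lower, adjusted p = 0.039), and the hypertrophy list -0.28 (14 of 17, adjusted p = 0.036). The p53 list had a median of -0.12 (20 of 28, adjusted p = 0.019), the histone modifiers -0.1 (20 of 33, adjusted p = 0.026, 0.02 without vehicle-treated wild-type replicate 3) and the antioxidant enzymes -0.04 (22 of 29, adjusted p = 0.049). The atrial markers lay lower with a median of -0.67 (11 of 12, adjusted p = 0.036). The nerve and Schwann cell markers lay higher with a median of 0.11 (10 of 13, adjusted p = 0.046), with Th, tyrosine hydroxylase, at 0.76 (SE 0.5). The vehicle values of Th, 8.22 to 9.96, overlapped its AZT-treated values, 9.29 to 10.22. The nerve list was no longer called with the slide as a block (adjusted p = 0.068), and its median was -0.06 without AZT-treated wild-type replicate 1. Snap25, a synaptic gene of that list, lay above 2 times the random-probe level on 0 of 4 vehicle and 1 of 3 AZT-treated arrays (replicate 1, at 10.57), so no difference is given. For the circadian and p53 lists the adjusted p = 0.17 with an estimated correlation. For the other lists given here the adjusted p = 0.74 with an estimated correlation. Here 1 of 3 AZT-treated arrays carried the atrial and Y-linked signal against 2 of 4 with vehicle, and with that signal as a block the atrial median was 0.11 (adjusted p = 0.91). In that fit, chosen after seeing the data, the immediate early genes had a median of -0.09 and kept the call (adjusted p = 0.025), as did the nerve markers at 0.30 (adjusted p = 0.0014). It no longer called 4 more lists: hypertrophy at -0.05 (adjusted p = 0.45), endoplasmic reticulum stress at -0.04 (adjusted p = 0.5), the glucocorticoid and fasting genes at -0.06 (adjusted p = 0.11) and antioxidant enzymes at -0.05 (adjusted p = 0.34). It called 4 others: calcium handling at -0.13 (adjusted p = 0.012), and the markers of macrophages at 0.19 (adjusted p = 0.026), erythroid cells at 0.35 (adjusted p = 0.002) and adipocytes at 0.18 (adjusted p = 0.023). Of its 20 calls 0 held (adjusted p = 0.1 to 0.69 with an estimated correlation).

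The 10 named genes with the smallest p in this comparison did not pass either. Higher values were found for Ap3b2, an adaptor subunit of neurons, at 1.25 (SE 0.38), Stmn2 at 0.93 (0.60 without AZT-treated wild-type replicate 1), Rhox2b at 0.87 (SE 0.28), Xlr5b at 0.78 (SE 0.25), Cfap74 at 0.77, Gal (galanin) at 0.69 and Tssk2 at 0.5. The lower ones were Corin, the protease that activates the natriuretic peptide, at -0.68 (SE 0.23), Tox3 at -0.79 and Slc25a33. AZT-treated wild-type replicate 1 had the highest level of its group for the neuronal genes Ap3b2 (10.49), Stmn2 (12.4) and Th (10.22), as for Snap25. Limma gave 0 genes with an adjusted p under 0.05 and 222 with an unadjusted p under 0.05, where 1323 would arise by chance, and 0 list members passed when adjusted over the list alone. Of 35 splits of the arrays compared into groups of these sizes, the real grouping included, 32 gave as many at that unadjusted level. The highest of the others gave 4870. The main fit leaves the split by Y-linked transcripts in the spread between replicates. With that signal as a block, limma gave 503 genes at that unadjusted level and 0 past the threshold. Leaving out 1 array gave from 153 (without vehicle-treated wild-type replicate 2) to 621 (without AZT-treated wild-type replicate 1). Of the 21 lists called (2 higher and 19 lower), 0 held with an estimated correlation and 0 kept the call without each array in turn, and without AZT-treated wild-type replicate 2 there were 6 calls.

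AZT against vehicle in MCAT hearts asks the same of mice with the transgene. The mitochondrial lists named next lay higher. Others did not pass: complex I (median 0.04, adjusted p = 0.086), complexes II to V (0.04, adjusted p = 0.058), mitochondrial DNA maintenance and transcription (0.16, adjusted p = 0.082), biogenesis regulators (0.21, adjusted p = 0.056), and dynamics and mitophagy (0.16, adjusted p = 0.089). All 23 measured members of the tricarboxylic acid cycle list were higher under AZT, with a median log2 difference of 0.31 (camera adjusted p = 8.3e-06). Fatty acid oxidation genes had a median of 0.33, with 26 of 29 higher (adjusted p = 8.6e-06). Mitochondrial ribosome genes had a median of 0.23, with 39 of 46 higher (adjusted p = 2.9e-05), and antioxidant enzymes 0.25, with 25 of 29 higher (adjusted p = 0.0029). The interferon response list lay lower, with a median of -0.26 and 30 of 33 members lower (adjusted p = 0.00036). These 5 calls did not hold with a correlation estimated from the data (adjusted p = 0.8 with an estimated correlation for each). No single gene passed limma's adjusted threshold.

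Of the tricarboxylic acid cycle, Sdhc, a membrane subunit of succinate dehydrogenase, differed by 0.69 (SE 0.26), Suclg2 by 0.9 (SE 0.39) and Pdha1, a subunit of pyruvate dehydrogenase, by 0.62 (SE 0.28). Of fatty acid oxidation, the thioesterase gene Acot2 differed by 1.42 (SE 0.58), Hadhb by 0.47 (SE 0.21) and Echs1 by 0.49 (SE 0.23). The mitochondrial ribosomal genes Mrps30 and Mrpl15 differed by 0.94 (SE 0.42) and 0.73 (SE 0.33), and Glrx3 among the antioxidant genes by 0.74 (SE 0.31). Ppargc1a, the coactivator that drives mitochondrial biogenesis, stood at 13.01 ± 0.79 (SD, n = 4) under AZT and 11.86 ± 0.41 (SD, n = 4) under vehicle, a difference of 1.15 (SE 0.41) with no overlap between the groups. Over all genes tested 2.5% had no overlap in this comparison, where chance gives 2.9%. Without AZT-treated MCAT replicate 4 Ppargc1a stood at 0.76 and Mrpl15 at 0.46, and without vehicle-treated MCAT replicate 3 Hadhb stood at 0.30. In the interferon list Irf7 differed by -0.87 (SE 0.32) and Igtp by -0.81 (SE 0.35). The hypertrophy list lay higher (median 0.3, 14 of 17 higher, adjusted p = 0.016), with Xirp1 at 0.94 (SE 0.32). The endoplasmic reticulum stress list also lay higher (median 0.36, 16 of 19, adjusted p = 0.016), with the chaperone gene Hspa5 at 0.54 (SE 0.37) and the stress sensor gene Ern1 at 0.52 (SE 0.25). Calcium handling and ion channel genes had a median of 0.15 (21 of 30 higher, adjusted p = 0.037), with Trdn (triadin) at 0.82 (SE 0.34) and the ryanodine receptor gene Ryr2 at 0.73 (SE 0.36). Neutrophil markers lay lower (median -0.32, 12 of 14, adjusted p = 0.04), with Elane, neutrophil elastase, at -0.62 (SE 0.24). Without vehicle-treated MCAT replicate 4 Hspa5 and Trdn stood at 0.34 and 0.47, and without replicate 2 of that group Elane at -0.39. On replicates 1 and 2, with Y-linked transcripts, Suclg2 stood at 12.69 and 12.87 under vehicle and 12.81 and 13.03 under AZT. On replicates 3 and 4 it stood at 11.52 and 11.57 against 12.46 and 13.93. Sdhc, Acot2, Hadhb, Mrps30, Xirp1, Hspa5, Ern1 and Trdn were also lower on both of vehicle replicates 3 and 4 than on either of 1 and 2. Pdha1, Echs1, Mrpl15, Glrx3, Ppargc1a and Ryr2 did not split so. For the endoplasmic reticulum stress list the adjusted p = 0.82 with an estimated correlation. For the hypertrophy, calcium handling and neutrophil lists the adjusted p = 0.8 with an estimated correlation. The atrial markers had a median of 0.53 with 11 of 12 higher, which did not pass (adjusted p = 0.11) and passed with the Y-linked signal as a block (adjusted p = 0.00093), a fit chosen after seeing the data. That fit does not level atrial content among arrays that carry the signal. The atrial marker Bmp10 was 9.11 and 12.36 on replicates 1 and 2 under vehicle, and 14.92 and 14.1 under AZT. In that fit the calcium handling list (median 0.15, adjusted p = 0.053) and the neutrophil markers (median -0.32, adjusted p = 0.057) were no longer called, while macrophage markers were (median 0.26, adjusted p = 0.014). Of its 9 calls 0 held (adjusted p = 0.66 with an estimated correlation).

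The named genes with the smallest p were Ntsr2, a neurotensin receptor gene, at 1.16 (SE 0.2, unadjusted p = 4.7e-05 and adjusted p = 0.86 from limma) and Zfp385b at 1.55. Wdcp and Ppp1r3a, a glycogen-targeting phosphatase subunit, were above 2 times the random-probe level on 0 of 4 vehicle-treated arrays. With values under that level raised to it, their means were higher under AZT by 2.13-fold and 2.07-fold (adjusted p = 0.86 from limma for each). These folds are lower bounds as to background only, and not as to the spread between arrays. The genes also included Wipi1 at 0.84, Hsd17b7, an enzyme of cholesterol synthesis, at 1.36, Acyp1 at 0.79, Ap5m1 at 1.42, Arhgap5 at 1.88 and Mical1 at -1.06. Arhgap5 was above 2 times the random-probe level on 1 of 4 vehicle-treated arrays, so the size of its difference is uncertain. Limma gave 0 genes with an adjusted p under 0.05 and 1374 with an unadjusted p under 0.05, against 1323 by chance, and 1 list member passed when adjusted over the list alone. Of 35 splits of these arrays, the real grouping included, 14 gave as many at that unadjusted level, and the highest other gave 5817. With the Y-linked signal as a block, limma gave 2816 genes at that unadjusted level and 0 past the threshold. Leaving out 1 array gave from 825 (without AZT-treated MCAT replicate 4) to 2920 (without replicate 3) at that level. Of the 9 lists called (7 higher and 2 lower), 0 held with an estimated correlation. Without AZT-treated MCAT replicate 4 the number of lists was 5, and the medians of the fatty acid oxidation, tricarboxylic acid cycle and mitochondrial ribosome lists were 0.13, 0.14 and 0.09, the last no longer called.

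**Figure D2:**
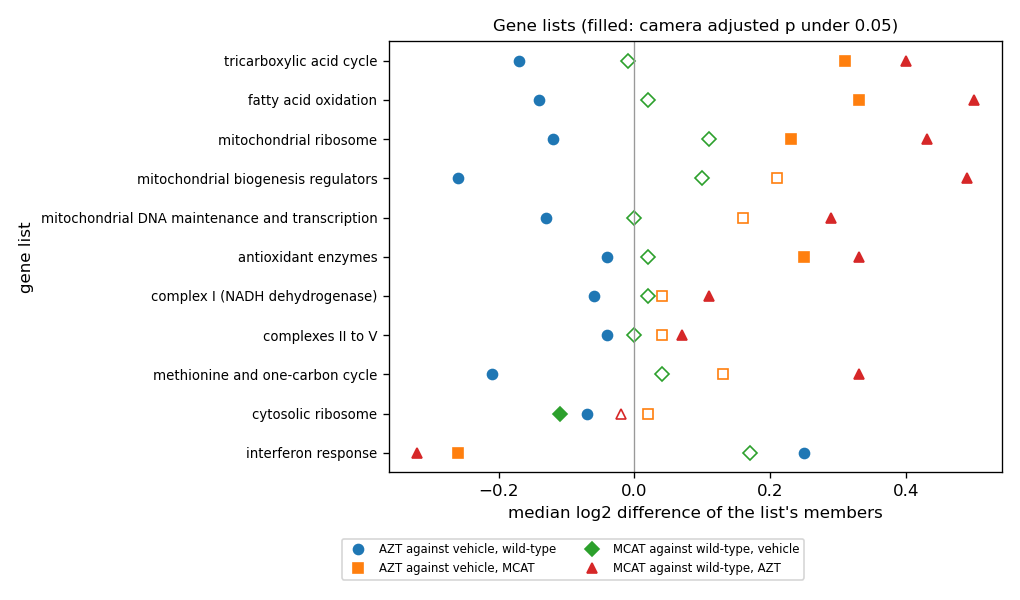
Median log2 difference (x axis) of the measured members of 11 gene lists (y axis) in the comparisons of AZT with vehicle and of MCAT with wild-type; each symbol is a list in a comparison, and filled symbols have a camera adjusted p under 0.05. The tricarboxylic acid cycle list lay at -0.17 for AZT in wild-type hearts, at 0.31 for AZT in MCAT hearts and at 0.4 for MCAT against wild-type under AZT.

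MCAT against wild-type under vehicle asks what the transgene alone changed. Cytosolic ribosomal protein genes lay slightly lower in MCAT hearts, with a median log2 difference of -0.11 and 43 of 49 members lower (camera adjusted p = 1.5e-06). Immediate early genes had a median of -0.3, with 18 of 23 lower (adjusted p = 0.003), and histone modifiers a median of -0.08, with 18 of 33 lower (adjusted p = 0.037). Cell cycle genes lay higher by a median of 0.16, with 24 of 29 higher (adjusted p = 0.049), a call lost with the slide as a block (adjusted p = 0.058). The histone modifiers stood at 0.08 without vehicle-treated wild-type replicate 3, and the immediate early genes at -0.08 without replicate 1 of that group. These 4 calls did not hold with a correlation estimated from the data (adjusted p = 0.98 with an estimated correlation for each). No single gene passed limma's adjusted threshold.

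In the ribosomal list Rps13 and Rps2 differed by -0.44 (SE 0.23) and -0.28 (SE 0.17), Rps13 by -0.29 without vehicle-treated MCAT replicate 4. Of the histone modifiers, the demethylase gene Kdm5a differed by -1.25 (SE 0.37), the demethylase gene Kdm6b by -0.68 (SE 0.28), the methyltransferase gene Setd7 by -0.71 (SE 0.29) and the acetyltransferase gene Ep300 by -0.58 (SE 0.26). Kdm5a, Kdm6b and Ep300, but not Setd7, were lower on both of vehicle-treated MCAT replicates 3 and 4 than on either of 1 and 2. The immediate early genes Klf6 and Jun differed by -0.88 (SE 0.46) and -0.71 (SE 0.49). Klf6 stood at -0.43 without vehicle-treated MCAT replicate 4, and Jun at -0.31 without vehicle-treated MCAT replicate 3 and 0.02 within the arrays with Y-linked transcripts. The level of Klf6 was 14.51 and 14.61 on vehicle-treated MCAT replicates 1 and 2, and 12.8 and 12.18 on replicates 3 and 4. It was 14.6 on each of vehicle-treated wild-type replicates 1 and 2, and 14.24 and 14.15 on replicates 3 and 4 of that group. In the cell cycle list the mitotic kinase gene Aurkb differed by 0.59 (SE 0.24), while Bub1 was above 2 times the random-probe level on 0 of 4 wild-type and 1 of 4 MCAT arrays. The atrial markers had a median of -0.31 with 9 of 12 lower, which did not pass (adjusted p = 0.16) and passed with the Y-linked signal as a block (adjusted p = 0.0034). That fit, chosen after seeing the data, also called extracellular matrix genes (median -0.11, adjusted p = 0.0082), mesothelium and epicardium markers (-0.31, adjusted p = 0.0082) and the hypertrophy list (-0.15, adjusted p = 0.046) lower. It called the interferon response (0.17, adjusted p = 0.043) higher in MCAT hearts. Of its 9 calls 0 held (adjusted p = 0.76 to 0.79 with an estimated correlation). The block takes the signal as present or absent. Among the arrays that carry it, vehicle-treated MCAT replicates 1 and 2 had the lowest Bmp10, an atrial marker (9.11 and 12.36, the others 14.06 to 14.92). Sln was also lowest there (13.46 and 14.45, the others 14.64 to 14.99), while mesothelial Upk3b was low on replicate 1 (11.43) but not 2 (13.68). These calls were not told apart from unequal tissue content. The 10 named genes with the smallest p were all lower in MCAT hearts: Resf1 at -1.5 (SE 0.35), and the zinc finger genes Zfp442 at -0.89, Zfp609 at -0.83 and Zbed6 at -1.03. The others were the cardiac transcription factor gene Gata6 at -1.46 (SE 0.39), the methyltransferase gene Ash1l at -1.6 (SE 0.44), Bach1, a repressor of antioxidant genes, at -1.7 (SE 0.47), Pcdh7 at -0.98, Csnk1g1 at -1.32 and Wipi1 at -0.73. Their adjusted p from limma was 1. On vehicle-treated MCAT replicates 1 and 2, with Y-linked transcripts, Bach1 stood at 10.25 and 10.38. On replicates 3 and 4, without them, it stood at 8.52 and 8.46. Its vehicle-treated wild-type values lay between 10.74 and 11.49, with replicates 3 and 4, also without them, at 11.49 and 11.33. The AZT-treated arrays without them stood at 11.23 and 10.67 in MCAT (replicates 3 and 4) and 10.85 and 9.01 in wild-type hearts (replicates 2 and 3). The low level of Bach1 thus did not follow Y-linked status across the groups. Ash1l, Csnk1g1, Zfp609 and Wipi1 were also lower on both of MCAT replicates 3 and 4 than on either of 1 and 2. Resf1, Zfp442, Gata6, Pcdh7 and Zbed6 did not split so.

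Cat, the mouse catalase gene on chromosome 2 (103294158 to 103325267 on mouse build MM9), stood at 12.54 ± 0.42 (SD, n = 4) in vehicle-treated wild-type and 12.78 ± 0.16 (SD, n = 4) in vehicle-treated MCAT hearts. The difference was 0.24 (SE 0.25, limma adjusted p = 1), and 0.04 without vehicle-treated wild-type replicate 3. Under AZT it stood at 12.53 ± 0.24 (SD, n = 3) and 13.02 ± 0.39 (SD, n = 4), a difference of 0.49 (SE 0.27, limma adjusted p = 0.68) with no overlap between the groups. It was 0.30 without AZT-treated MCAT replicate 4. Under AZT 6.8% of all genes tested had no overlap between MCAT and wild-type hearts, where chance gives 5.7%. The labels do not give the sequence of the transgene, so probes for the mouse gene need not detect it and these values do not check the genotypes. For MCAT against wild-type under vehicle, limma gave 0 genes with an adjusted p under 0.05 and 392 with an unadjusted p under 0.05, against 1323 by chance. Of 35 splits of these arrays, the real grouping included, 30 gave as many at that unadjusted level, and the highest other gave 6300. No list member passed when adjusted over the list alone. With the Y-linked signal as a block, limma gave 888 genes at that unadjusted level and 0 past the threshold. Leaving out 1 array gave from 281 (without vehicle-treated wild-type replicate 2) to 693 (without vehicle-treated MCAT replicate 1). Of the 4 lists called (1 higher and 3 lower), 0 held with an estimated correlation, and 14 were called without vehicle-treated MCAT replicate 2.

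MCAT against wild-type under AZT asks how the transgene altered the treated heart, and here the mitochondrial lists lay higher in MCAT hearts. Mitochondrial ribosome genes were higher in MCAT hearts by a median log2 difference of 0.43, with 41 of 46 higher (camera adjusted p = 4.5e-11). Fatty acid oxidation genes were higher by a median of 0.5, with 25 of 29 higher (adjusted p = 6.2e-08). Tricarboxylic acid cycle genes were higher by 0.4, with 21 of 23 higher (adjusted p = 8.2e-08), and antioxidant enzymes by 0.33, with 26 of 29 higher (adjusted p = 7.7e-05). Interferon response genes were lower by a median of -0.32, with 29 of 33 lower (adjusted p = 0.00022). These calls did not hold with an estimated correlation (adjusted p = 0.43 with an estimated correlation for each of these 5 lists), and no single gene passed limma's adjusted threshold.

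The biogenesis regulators had a median of 0.49, with 9 of 13 higher (camera adjusted p = 0.0007, and adjusted p = 0.43 with an estimated correlation). Esrrg, on chromosome 1 (189821737 to 190038763), stood at 9.39 ± 1.1 (SD, n = 4) in MCAT and 7.08 ± 0.58 (SD, n = 3) in wild-type hearts, a difference of 2.31 (SE 0.59). Its wild-type values were above 2 times the random-probe level on 1 of 3 arrays, and 1 of 3 lay at or under that level itself, so the size of this difference is uncertain. Ppargc1a, on chromosome 5 (51848892 to 51945055), stood at 13.01 ± 0.79 (SD, n = 4) and 11.52 ± 0.41 (SD, n = 3), a difference of 1.48 (SE 0.44). Tfam, on chromosome 10 (70688224 to 70698050), stood at 11.74 ± 0.56 (SD, n = 4) and 10.56 ± 0.36 (SD, n = 3), a difference of 1.17 (SE 0.36). All 4 MCAT values lay above all 3 wild-type values for each of these genes. Over all genes tested 6.8% had no overlap in either direction, where chance gives 5.7%. The adjusted p of Esrrg, Ppargc1a and Tfam over all genes was 0.66 with limma, while 3 of the 13 list members were higher when adjusted over the list alone. Of the 20 genes for mitochondrial DNA maintenance and transcription, 15 were higher (median 0.29, camera adjusted p = 0.00099, and adjusted p = 0.43 with an estimated correlation) and 5 were higher when adjusted over the list alone. Examples were Mgme1 at 0.88 (SE 0.23) and Opa1, a gene of inner membrane fusion, at 0.98 (SE 0.31). Polg2, the accessory subunit of the mitochondrial DNA polymerase, is among the 5, but was above 2 times the random-probe level on 0 of 3 wild-type and 1 of 4 MCAT arrays, so no difference is given.

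**Figure D3:**
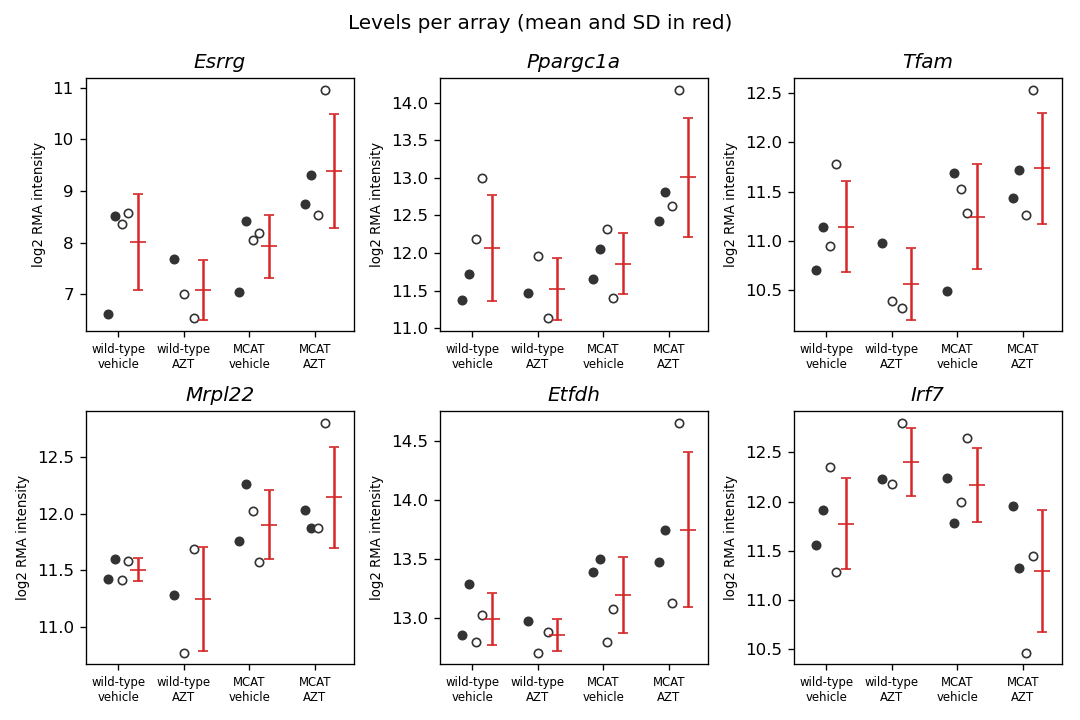
Levels of Esrrg, Ppargc1a, Tfam, Mrpl22, Etfdh and Irf7 (y axis, log2 RMA intensity) in the 4 groups (x axis); each circle is an array, filled where it carried the Y-linked and atrial signal and open where it did not, and the red mark and bar give the mean and SD. For Esrrg the AZT-treated MCAT mean was 9.39 and the AZT-treated wild-type mean 7.08, and AZT-treated MCAT replicate 4 lay highest at 10.96.

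Among the mitochondrial ribosome genes Mrpl22 differed by 0.89 (SE 0.27), Mrpl15 by 1.09 (SE 0.35) and Mrpl2 by 0.73 (SE 0.26). Of the fatty acid oxidation genes, Etfa and Etfdh, which pass electrons from acyl-CoA dehydrogenases to the respiratory chain, differed by 0.84 (SE 0.28) and 0.9 (SE 0.31), and Cpt2, which re-forms acyl-CoA inside mitochondria, by 0.86 (SE 0.3). Dlat and Sdhd of the tricarboxylic acid cycle list differed by 0.97 (SE 0.38) and 0.76 (SE 0.27), Sod2, the mitochondrial superoxide dismutase, by 0.74 (SE 0.31) and Glrx3 by 0.89 (SE 0.33). Of the respiratory chain, complex I had a median of 0.11 (27 of 36 higher, camera adjusted p = 0.0049), with Ndufv2 at 0.82 (SE 0.29). Complexes II to V had a median of 0.07 (26 of 42 higher, adjusted p = 0.0054), with Cycs (cytochrome c) at 0.73 (SE 0.23). Both lists had an adjusted p = 0.78 with an estimated correlation. Interferon genes named by the rule were Irf7 at -1.11 (SE 0.35), Rsad2 at -0.59 (SE 0.21) and Tap1 at -0.91 (SE 0.33).

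Methionine and one-carbon genes had a median of 0.33 (17 of 22 higher, camera adjusted p = 0.0054, and adjusted p = 0.23 with an estimated correlation), with Mthfd2l, a mitochondrial folate enzyme, at 1.35 (SE 0.34). In this list 1 member was higher when adjusted over the list alone. Protein folding genes had a median of 0.25 (24 of 29 higher, adjusted p = 0.0019), with the mitochondrial chaperonin gene Hspe1 at 0.74 (SE 0.31). Mitochondrial dynamics and mitophagy genes had a median of 0.17 (11 of 17, adjusted p = 0.0084), with Bnip3, a mitophagy receptor, at 1.6 (SE 0.52). These 2 lists had an adjusted p = 0.43 with an estimated correlation. Endoplasmic reticulum stress genes had a median of 0.43 (17 of 19, adjusted p = 0.0055) and the hypertrophy list 0.4 (15 of 17, adjusted p = 0.021). Hypoxia genes had a median of 0.38 (12 of 19, adjusted p = 0.031), with the prolyl hydroxylase gene Egln3 at 1.03 (SE 0.42). The glucocorticoid and fasting genes had a median of 0.45 (15 of 20, adjusted p = 0.033) and the p53 list 0.15 (19 of 28, adjusted p = 0.048). The hypoxia and p53 lists had an adjusted p = 0.38 with an estimated correlation, and the other 3 an adjusted p = 0.81 with an estimated correlation. The 12 measured atrial markers were all higher, with a median of 0.72 that did not pass (adjusted p = 0.076), beside 2 of 4 MCAT and 1 of 3 wild-type arrays with the atrial signal. With that signal as a block the atrial median was 0.16 and the mitochondrial ribosome, fatty acid oxidation and tricarboxylic acid cycle medians were 0.5, 0.47 and 0.4. In that fit the hypertrophy list (0.29, adjusted p = 0.064), the glucocorticoid and fasting genes (0.23, adjusted p = 0.09) and the p53 list (0.19, adjusted p = 0.053) were no longer called. The slide as a block also ended the p53 call (adjusted p = 0.054) and called the atrial markers higher (adjusted p = 0.043), both at the preset correlation. With the Y-linked signal as a block, markers of 6 other cell types were called lower in MCAT hearts beside the mitochondrial lists. They were endothelial cells (-0.16, adjusted p = 0.016), mesothelium and epicardium (-0.48, adjusted p = 0.03), smooth muscle and pericytes (-0.33, adjusted p = 0.033), erythroid cells (-0.34, adjusted p = 0.039), nerve and Schwann cells (-0.39, adjusted p = 0.039) and neutrophils (-0.33, adjusted p = 0.048). Calcium handling was called higher (0.1, adjusted p = 0.033). Of the 21 calls of that fit 0 held (adjusted p = 0.45 to 0.6 with an estimated correlation).

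The 10 named genes with the smallest p differed without overlap between the groups, as did 6.8% of all genes tested, where chance gives 5.7%, and their adjusted p was 0.66 with limma. Rhox2b and Xlr5b, members of X-linked multicopy families whose copies the probes may share, were lower in MCAT hearts at -1.47 (SE 0.28) and -1.28 (SE 0.25), as were Cfap74 at -1.05 and Grin1, a glutamate receptor subunit gene, at -1.12. Cep112 at 1.3, Hsd17b7 at 1.59 (SE 0.36), the kinase gene Prkca at 1.52 (SE 0.35), Tox3 at 1.16, Acyp1 at 0.89 and Hat1, a histone acetyltransferase gene, at 1.32 were higher. Limma gave 0 genes with an adjusted p under 0.05 and 1936 with an unadjusted p under 0.05, against 1323 by chance, and 10 list members passed when adjusted over the list alone. Of 35 splits of these arrays, the real grouping included, 8 gave as many at that unadjusted level, and the highest other gave 7903. With the Y-linked signal as a block, limma gave 3057 genes at that unadjusted level and 0 past the threshold. Leaving out 1 array gave from 809 (without AZT-treated wild-type replicate 3) to 3477 (without AZT-treated MCAT replicate 3) at that level. With array weights 2721 genes passed, but 0 did once Y-linked status was added as a block, and 5 of 35 splits of the arrays, the real grouping included, gave as many. Of the 17 lists called (16 higher and 1 lower), 0 held with an estimated correlation, and the mitochondrial ribosome median was 0.28 without AZT-treated MCAT replicate 4. The median of the mitochondrial DNA list was 0.10, Etfdh 0.60 and Egln3 0.65 without that array.

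The test of whether the AZT response differed between MCAT and wild-type hearts took the AZT difference in MCAT minus that in wild-type hearts. A positive value can come from a rise in MCAT hearts, a fall in wild-type hearts or both. All 23 tricarboxylic acid cycle genes were positive, with a median difference between the responses of 0.41 (camera adjusted p = 8.5e-06). Fatty acid oxidation genes had a median of 0.51 (26 of 29 positive, adjusted p = 1.3e-05), mitochondrial ribosome genes 0.34 (38 of 46, adjusted p = 3.4e-05) and antioxidant enzymes 0.32 (24 of 29, adjusted p = 0.0038). Interferon response genes had a median of -0.59 (27 of 33 negative, adjusted p = 8.3e-05). These calls did not hold with an estimated correlation (adjusted p = 0.7 with an estimated correlation for each of these 5 lists), and no single gene passed limma's adjusted threshold.

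Examples from these lists, none past the threshold, were Suclg2 at 1.34 (SE 0.58), Acot2 at 2.05 (SE 0.85), Mrpl15 at 1.07 (SE 0.48), Irf7 at -1.5 (SE 0.47), Igtp at -1.37 (SE 0.51) and Gbp3 at -1.45 (SE 0.55). Esrrg and Ppargc1a of the biogenesis regulators (list median 0.29, adjusted p = 0.0076, and adjusted p = 0.7 with an estimated correlation) differed by 2.39 (SE 0.8) and 1.7 (SE 0.6). The muscle ubiquitin ligase genes Trim63 and Fbxo32 differed by 1.09 (SE 0.35) and 1.47 (SE 0.48), the potassium channel gene Kcnd2 by 0.89 (SE 0.35) and S100a9, a neutrophil gene, by -1 (SE 0.41). The named genes with the smallest p were Ntsr2 at 1.61 (SE 0.3, limma adjusted p = 0.81), Tox3 at 1.64, Zfp385b at 2.4, and Ap5m1 at 2.22. Wdcp was also among them, near background in vehicle-treated MCAT hearts. The others were Acyp1 at 1.2, Gata6 at 2.38, Arhgap5 at 2.85, Rhox2b at -1.75 and Xlr5b at -1.43. Limma gave 0 genes with an adjusted p under 0.05 and 1549 with an unadjusted p under 0.05, against 1323 by chance, and 1 list member passed when adjusted over the list alone. Of 100 splits of the arrays, the real grouping included, 35 gave as many at that unadjusted level, and the highest other gave 6331. With the Y-linked signal as a block, limma gave 2489 genes at that unadjusted level and 0 past the threshold. Leaving out 1 array gave from 718 (without AZT-treated wild-type replicate 3) to 2741 (without AZT-treated MCAT replicate 3) at that level. Of the 20 lists called (18 positive and 2 negative), 0 held (adjusted p = 0.7 to 0.77 with an estimated correlation), and without AZT-treated wild-type replicate 2 only 8 were called. With the Y-linked signal as a block, mitochondrial dynamics and mitophagy (0.27, adjusted p = 0.05), the cytosolic ribosome (0.07, adjusted p = 0.056) and immediate early genes (0.29, adjusted p = 0.056) were no longer called. Nerve and Schwann cell markers (-0.65, adjusted p = 0.042) and adipocyte markers (-0.25, adjusted p = 0.044) were then called. Of the 19 calls of that fit 0 held (adjusted p = 0.61 with an estimated correlation).

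Genes of cardiac stress and of thymidine handling fixed beforehand did not pass in any of the 5 comparisons. Nppb, the B-type natriuretic peptide gene, differed by 0.41 (SE 0.21) for AZT in MCAT hearts and by -0.09 (SE 0.23) in wild-type hearts, and Nppa by 0.13 (SE 0.43) and -0.11 (SE 0.46). Nppa lay between 15.37 and 15.57 on the 7 arrays with Y-linked transcripts and between 14.01 and 14.87 on the 8, and with that signal as a block its wild-type difference was 0.07. Myh7, the beta myosin heavy chain gene, differed by -0.89 (SE 0.49) and -0.28 (SE 0.53). It stood at -0.45 in MCAT hearts without AZT-treated MCAT replicate 3 and at -0.06 in wild-type hearts without vehicle-treated wild-type replicate 2. The mitochondrial stress hormone gene Gdf15 differed by 0.01 (SE 0.35) in MCAT and 0.47 (SE 0.38) in wild-type hearts. Its wild-type value was 0.20 without vehicle-treated wild-type replicate 4. Values near 0, those of Gdf15 in MCAT hearts, Nppb in wild-type hearts, and Nppa, Cdkn1a, Tk1 and Tk2 in both, changed sign when some array was left out. Fgf21, another such gene, was above 2 times the random-probe level on 1 array at most of each group, so no difference is given. The p53 target Cdkn1a differed by 0.13 (SE 0.32) in MCAT and 0.08 (SE 0.35) in wild-type hearts. Tk2, the mitochondrial thymidine kinase gene, differed by -0.04 (SE 0.2) and -0.01 (SE 0.21), and Tk1, its cytosolic counterpart, by -0.12 (SE 0.51) and -0.09 (SE 0.55). The list of nucleoside and thymidine handling had a median of -0.01 for AZT in wild-type and -0.13 in MCAT hearts (camera adjusted p = 0.95 and 0.42).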

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

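The tests of dissection, sex, slide, share of arrays with Y-linked transcripts and array weights, and the splits behind the counts of genes, were chosen after the result was seen. The patterns weighed were picked from the results. The bounds for a single array and for the other splits were written before those values were seen, but the need to pass the bound for a single array by more than the spread was added after its value.

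Of 318 pairs of a gene and a group with 4 arrays, over the 106 genes examined, 20 had an array far from the rest of its group by Dixon's test, where 15.9 would arise by chance at 1 in 20. AZT-treated MCAT replicate 4 held 6 of them: Slc25a33 at 13.06 against 11.19 to 11.37 in the rest of its group, Cat at 13.61 against 12.80 to 12.85, Trdn at 14.16 against 13.45 to 13.49, Mrpl22 at 12.80 against 11.87 to 12.03, Cycs at 14.82 against 14.22 to 14.26 and Egln3 at 14.22 against 12.68 to 12.71, all higher. Vehicle-treated wild-type replicate 4 held 5, also higher: Hsph1 at 12.86, Sod2 at 14.26, Pdha1 at 14.14, Hspe1 at 13.48 and Kcnd2 at 9.99. Vehicle-treated wild-type replicate 3 was lower for Acadl at 13.67, Mrpl15 at 10.78 and Mrpl2 at 12.55, and AZT-treated MCAT replicate 3 for Myh7 at 11.09, Arhgap5 at 8.17 and Rps2 at 14.67. Single cases were Esrrg at 6.62 in vehicle-treated wild-type replicate 1 against 8.36 to 8.57, Zfp385b at 11.11 in replicate 2 of that group and Pcdh7 at 11.19 in vehicle-treated MCAT replicate 1.

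The AZT response differed between MCAT and wild-type hearts for 20 gene lists by camera, with a median difference between the responses for each. Mitochondrial and metabolic lists were fatty acid oxidation at 0.51, the tricarboxylic acid cycle at 0.41, the mitochondrial ribosome at 0.34, antioxidant enzymes at 0.32, biogenesis regulators at 0.29, methionine and one-carbon genes at 0.24, mitochondrial DNA maintenance and transcription at 0.22, dynamics and mitophagy at 0.19, complex I at 0.09 and complexes II to V at 0.07. Stress and other lists were atrial markers at 0.94, endoplasmic reticulum stress at 0.57, hypertrophy at 0.53, immediate early genes at 0.50, glucocorticoid and fasting genes at 0.49, calcium handling and ion channels at 0.21, protein folding at 0.17 and the cytosolic ribosome at 0.10. The interferon response at -0.59 and neutrophil markers at -0.39 were negative. Of these 20 calls 0 held (adjusted p = 0.7 to 0.77 with an estimated correlation). Only 1 of 3 AZT-treated wild-type arrays carried the Y-linked and atrial signal, and with that as a block the atrial median was 0.49, that of the glucocorticoid and fasting genes 0.29 and that of the immediate early genes 0.29. The list calls of the 5 comparisons share arrays and are not independent of each other.

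Under AZT the mitochondrial ribosome genes lay higher in MCAT than in wild-type hearts by a median of 0.43. An unequal share of arrays with Y-linked transcripts is argued against as the whole cause, since with that as a block the median was 0.5. Without AZT-treated MCAT replicate 4 the median was 0.28, which lay above the bound of 0.25 set beforehand by less than the spread of these medians, so dependence on a single array stays open. Of the 35 splits of the 7 arrays 3, the real grouping included, gave a shift as large, the highest of the others being 0.519, so chance cannot be excluded. An effect of the transgene in treated hearts stays open as the biological explanation.

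With array weights 2721 genes passed for MCAT against wild-type under AZT. A candidate explanation is that the weights tilted the comparison by Y-linked status, in opposite ways in the 2 groups. AZT-treated MCAT replicates 1 and 2, which have Y-linked transcripts, had weights of 1.85 and 2.76, and replicates 3 and 4, which lack them, 0.28 and 0.8. AZT-treated wild-type replicate 1, which has them, had 0.54, and replicates 2 and 3, which lack them, 0.88 and 2.71. With Y-linked status as a block the weights gave 0 genes in limma, with 3746 at an unadjusted p under 0.05 against 8734 without the block. Of the 35 splits with weights estimated anew 5, the real grouping included, gave as many genes, the highest of the others 8872, so chance cannot be excluded. An effect of the transgene on these genes was not told apart from the makeup of the weighted groups by any other test.

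Other splits of the same arrays gave as many lists, and as many genes at limma's unadjusted p under 0.05, too often to exclude chance in any comparison. For genes past the adjusted threshold the count was 0, which every split reaches by construction (35 of 35 in each of the 4 pairs of groups and 100 of 100 for the difference between the responses), so these counts test nothing. The highest of the other splits gave 0 genes for AZT in wild-type hearts, 0 for AZT in MCAT hearts, 9.8% of the genes tested for MCAT under vehicle, 7.6% for MCAT under AZT and 0 genes for the difference. The split with 9.8% was the one that set the arrays with Y-linked transcripts most fully apart from the rest. For AZT in MCAT hearts the split that set them as fully apart gave 0 genes, so this structure was not shown to be the reason. For the split with 7.6% it was not shown either, since 4 other splits set them as far apart and gave 0 genes. For lists, with the real grouping included in each count, 2 of 35 splits reached the 21 of AZT in wild-type hearts (highest other 23), 22 of 35 the 9 of AZT in MCAT hearts (22), 27 of 35 the 4 of MCAT under vehicle (23), 8 of 35 the 17 of MCAT under AZT (25) and 11 of 100 the 20 of the difference (25).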

How the results depend on the processing

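The alternatives that use Y-linked status were chosen after seeing the data and the others before. Leaving out each array in turn gave 0 genes past limma's threshold in every comparison, with 0 to 0 as the range. The number of gene lists ran from 6 (without AZT-treated wild-type replicate 2) to 20 (without replicate 1) for AZT in wild-type hearts, where the count was 21. It ran from 5 (without AZT-treated MCAT replicate 4) to 16 (without replicate 3) for AZT in MCAT hearts, where it was 9, and from 3 (without vehicle-treated wild-type replicate 1) to 14 (without vehicle-treated MCAT replicate 2) for MCAT under vehicle, where it was 4. It ran from 12 to 23 for MCAT under AZT, where it was 17, and from 8 to 22 for the difference between the responses, where it was 20, lowest without AZT-treated wild-type replicate 2 and highest without replicate 1. Calls kept without every array numbered 0, 2, 1, 9 and 5 lists in this order of comparisons.

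An estimated correlation gave 0 lists in each comparison, as did fry by direction (0) and fry for mixed changes (0). With the replicate block the counts of genes were 0 in each comparison and the lists numbered 12, 10, 4, 19 and 18, so that the count moved by over 1.5 times for AZT in wild-type hearts alone. With the slide as a block the lists numbered 21, 9, 3, 17 and 21 and the genes 0 in each comparison. Quantile normalization again gave 8 lists for AZT in wild-type hearts, 2 for MCAT under vehicle and 9 for the difference, and leaving out dim features gave 8, 2 and 6. Array weights gave 15 lists for AZT in MCAT hearts and 13 for MCAT under vehicle, gave 2721 genes for MCAT under AZT, and moved the median of all genes to -0.112 for the difference. An unadjusted p under 0.05 with a 1.5-fold change gave 171, 1114, 270, 1695 and 1539 genes.

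Within the 7 arrays with Y-linked transcripts, where AZT-treated wild-type has 1 array that is assumed to vary like the others, 1, 2, 7 and 5 lists were called for AZT in wild-type hearts, AZT in MCAT hearts, MCAT under AZT and the difference. Within the 8 without them MCAT under vehicle had 8 lists, and with Y-linked status as a block 9. That block with an estimated correlation gave 0 lists in each comparison. For AZT in wild-type hearts camera's direction, relative to all other genes, turned within the 7 arrays for 10 lists, with medians near 0: complex I at 0.02, complexes II to V at 0.02, mitochondrial DNA at 0.05, antioxidant enzymes at 0.07, fatty acid oxidation at -0.00, the tricarboxylic acid cycle at 0.03, hypertrophy at 0.03, protein folding at 0.04, endoplasmic reticulum stress at 0.08 and atrial markers at 0.02. For the difference it turned for complex I at -0.01, protein folding at -0.05 and immediate early genes at -0.11. For AZT in wild-type hearts the nerve markers turned in camera's direction with array weights (median 0.15) and without AZT-treated wild-type replicate 1 (-0.06, in a range up to 0.42). The mitochondrial ribosome turned without vehicle-treated wild-type replicate 4 (0.04, in a range from -0.19). The cause was not tested. Of 1735 list values under alternatives 1045 kept the call, 674 lost it and 16 turned, and of 9251 gene values 8894 moved by less than 1 SD between replicates and 357 by more, while 185 had the other sign. Of the 238 differences of named genes, none past limma's threshold, 85 moved toward 0 by over 1.5 times without some array, 28 had the other sign without some array and 52 under another alternative. Signal over background limits the dim features, and background correction of raw intensities was not run.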

Other observations

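The tests of the split by Y-linked transcripts were chosen after the result was seen, and the list tests at the end were not. The 7 arrays with Y-linked transcripts carried far more than atrial muscle transcripts. Of 26455 genes, 1363 lay wholly higher on those 7 arrays than on the other 8 and 757 lay wholly lower, where chance would give 8.2. The gene lists differed in this respect: 30 of 35 extracellular matrix genes, 14 of 16 fibroblast markers, 12 of 17 macrophage markers, 10 of 23 immediate early genes and 8 of 10 markers of the mesothelium and epicardium lay wholly higher. In contrast 0 members lay wholly higher or lower in complex I, complexes II to V, the tricarboxylic acid cycle and the cytosolic ribosome, which hold 36, 42, 23 and 49 measured genes. Upk3b and Msln, which mark mesothelium, lay between 11.43 and 13.68 and between 12.65 and 14.12 on the 7 arrays, and between 6.71 and 9.15 and between 8.43 and 11.11 on the 8. Fmod and Comp, matrix genes of tendon and cartilage, lay at 13.69 to 14.31 and 14.05 to 14.31 against 7.15 to 9.35 and 9 to 11.18. Hamp, the iron hormone hepcidin, lay at 12.31 to 14.41 against 6.13 to 8.52. Irx4, a transcription factor of ventricular muscle, lay at 10.01 to 11.6 on the 7 arrays and at 12.81 to 13.93 on the 8. No biological explanation among the study's groups was tested for this, because every group held arrays of both kinds.

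A candidate explanation is that the dissections of these 7 hearts held atrial, epicardial and perhaps valve tissue. Of the 12 measured atrial markers 10 lay wholly higher, as did 8 of 10 markers of the mesothelium and epicardium, while Irx4 lay lower, which is what such tissue would give. The ventricular cardiomyocyte markers test this little, since 13 of the 15 had a mean above 14, near the top of the scale. The slides are argued against, since within slide 1 alone the lowest Myl7 of the arrays with Y-linked transcripts lay 6.07 above the highest of the others. Sex of the animals cannot be told apart from dissection here, because the atrial and Y-linked signals disagreed on 0 of 15 arrays, so whether a gene on these arrays follows sex, dissection or both stays open. The labels used here give no sex. By Ddx3y and Xist the 7 arrays had the pattern of male and the other 8 that of female mice.

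Genes of the DNA methylation machinery, a theme of the series title, were not called as a list in any comparison. Their median was 0.02 for AZT in wild-type hearts (18 measured, camera adjusted p = 0.95), -0.19 for AZT in MCAT hearts (adjusted p = 0.56), 0.07 for MCAT under vehicle (adjusted p = 0.91), -0.12 for MCAT under AZT (adjusted p = 0.46) and -0.21 for the difference between the responses (adjusted p = 0.63). The NRF2 targets, which respond to oxidants, had medians of -0.03, 0.16, 0.02, 0.17 and 0.15 in the same order (26 measured, adjusted p = 0.37, 0.42, 0.97, 0.22 and 0.31).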
